A study of Drosophila melanogaster with 4 samples.

How the data were processed

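RNA was measured by sequencing in testes of Drosophila melanogaster of 2 genotypes, bam mutant and Phf7 bam double mutant, with 2 libraries per genotype and 4 libraries in all. Per the labels' protocols, testes were dissected in cold buffer from flies within 3 days of eclosion, RNA was selected with oligo-dT beads, and libraries were made with a directional kit. The labels call the libraries of a genotype biological replicates, so p-values measure the spread between such samples. The submitters' processing notes name TopHat2, Cufflinks, Cuffdiff and the genome build dm3, with no versions, roles or settings. The gene annotation and the use of strand in quantification are not given in the sources used here.

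The authors deposited 1 table per library with an FPKM, a fragment abundance scaled to transcript length and library size, for each of 14664 genes, per the file headers, together with lower and upper bounds of an interval and a status. The deposited FPKM lay outside its own interval for 13.1% to 16.9% of genes, so the bounds were not used as errors. The status was OK for 14597 genes in all 4 libraries. Summed FPKM lay between 650127 and 662056 per library. FPKM values are not counts, so no count test was run, and the absolute sequencing depth is unknown. The spacing of the lowest FPKM values, up to 0.15, was used to estimate relative depth: taking bam replicate 1 as 1, bam replicate 2 had a depth of 1.23, Phf7 bam replicate 1 of 1.16 and Phf7 bam replicate 2 of 1.42. These estimates rest on the most frequent ratio, which held for 20.9% to 24.0% of the low genes of a pair of libraries.

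An FPKM of exactly 0 was listed in genes that every cell uses, such as the threonyl-tRNA synthetase ThrRS in bam replicate 2. For a single gene it is therefore reported only as listed at 0, with no fold change. The tests and the median log2 ratios over sets of genes do include such values. Gene identifiers were matched to current symbols for 13335 genes, and 1329 kept the symbol in the tables. Of the genes written into lists 495 had values, and 15 were not analysed here. Coordinates are those of the deposited tables in dm3, counted from 1. The reference annotation used here is of a later build, so it supplied only gene class and strand, by identifier. Tested genes whose loci overlap were kept, and their values are uncertain where reads from both strands were counted together.

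Genes with a mean FPKM of at least 1 over the 4 libraries were tested, which left 8965. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 as a linear model of genotype, with empirical Bayes moderation and a trend on mean expression. Tests were two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Residual degrees of freedom were 2, and the prior added 2.64. Of 25 gene lists, 22 had at least 3 measured members and were tested with camera in limma. The other lists were the targeted genes, the cup and comet genes and the Y-linked genes. The camera test was run with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Adjusted p-values of lists were taken over the 22 lists. Fisher's exact test, two-sided, compared calls on X with calls on 2L, 2R, 3L and 3R, and calls within 1 Mb of Phf7 with the rest of X; 0.5 was added to each cell for odds ratios. Genes are not independent replicates in these tests. Joins and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

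The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Phf7, bam and Reepl1, the 10 largest increases and the 10 largest decreases among called genes with both Phf7 bam libraries beyond both bam libraries, and for each list up to 4 called members or, with none called, the member with the highest mean. Of the genes under this rule 1 is not reported here. Other genes were chosen after their values were seen. They are Kmn1, genes named as neighbours or overlaps of another gene, genes named for a listed 0 in a single library, list members named for passing when adjusted over the list alone, and those said in the text to have been chosen so. The settings varied were pseudocounts of 0.1 and 0.5, no filter on FPKM or a mean of at least 5, equal medians, quantile normalization, moderation without trend or with robust moderation, a minimum of 2-fold, a replicate block, status OK in all libraries, each library left out, and windows of 0.5 and 2 Mb. With a library left out, its genotype has 1 library, assumed to vary like the other genotype. A count test was planned only for the case of deposited counts and was not run. Added after seeing the data were a screened set, which kept genes with a locus of at least 200 bp and a value above 0 in all 4 libraries, the same with robust moderation, and a crossed pairing with and without the screen.

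The procedure was tested on simulated data with the spread of the 8965 genes and 50 genes per size of change. It recovered 36% of genes changed by 1 on the log2 scale, 82% at 2, 94% at 3 and 86% at 4. There were 8 false calls among 176, which also include genes of a list that was shifted. Robust moderation recovered 50%, 88%, 94% and 86%. These values describe the simulated data only, and whether they carry over to the measured libraries was not tested. In the measured libraries, setting bam replicate 2 and Phf7 bam replicate 1 against the other libraries gave 118 calls. The simulated false calls are therefore no estimate of the false calls among the measured genes.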

Results

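Transcriptomes were measured in testes of newly eclosed flies mutant for bam, and in testes mutant for both Phf7 and bam. The bam gene is needed for germ cells to leave the mitotic spermatogonial divisions, so that a bam mutant testis fills with early germ cells. Phf7 encodes a PHD finger protein known for its role in male germline identity. The comparison of the genotypes asks which transcripts differ in such testes when Phf7 is lost as well. Each genotype had 2 biological replicates. In each library 8650 to 8873 genes had an FPKM of at least 1, and CG18628 had the highest value of each, at 50450 to 53823 FPKM.

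Phf7 (CG9576 in the tables; dm3, X, 20054386 to 20056763) fell from 162.6 ± 14.96 FPKM (SD, n = 2) in bam testes to 20.8 ± 2.94 FPKM (SD, n = 2) in Phf7 bam testes. The difference was -2.91 on the log2 scale (SE 0.147, limma adjusted p = 0.00706), and transcript was still listed in both double mutant libraries, at 18.8 and 22.9 FPKM. The allele is not given in the labels, so it is open which part of the gene these values cover. bam itself (3R, 21068761 to 21070884) stood at 27.5 ± 1.5 and 30.1 ± 3.50 FPKM (SD, n = 2 each), a difference of 0.12 (SE 0.128, limma adjusted p = 0.955). The fall of Phf7 missed the threshold when either Phf7 bam library was left out, with the change at -2.77 without replicate 1 and -3.05 without replicate 2. Every call was lost in these fits, so the loss is not particular to Phf7. Over all settings its limma adjusted p ranged from 1.71e-82 to 0.141.

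Reepl1, a member of the REEP family of endoplasmic reticulum membrane proteins, and its neighbour Kmn1, which encodes a kinetochore protein, were both higher in the double mutant. Reepl1 (CG11697 in the tables; X, 11466740 to 11467673) stood at 0.62 and 0.25 FPKM in the bam libraries and at 12.7 and 12.9 FPKM in the Phf7 bam libraries, a change of 3.27 (SE 0.194, limma adjusted p = 0.0135; 2.45e-73 to 0.303 over all settings). Kmn1 (X, 11465400 to 11466475), which was named after its values were seen, rose from 5.57 ± 0.15 to 20.5 ± 0.752 FPKM (SD, n = 2 each), a change of 1.71 (SE 0.104, limma adjusted p = 0.0145). The loci lie head to head on opposite strands, 264 bp apart, and neither overlaps the other. On the other side of Kmn1, CG11699 overlaps it by 46 bp on the opposite strand. Reads of the shared end cannot be told apart if strand was not used in quantification. CG11699 was at 85.3 and 80.7 FPKM in bam and at 124 and 152 FPKM in Phf7 bam testes (change 0.72, limma adjusted p = 0.339, and 0.000440 with robust moderation). CG11696, which follows Reepl1, differed by 0.15 (limma adjusted p = 0.925), and Polr2A, the gene beyond CG11699, by 0.09 (limma adjusted p = 0.975). The call of Reepl1 was lost without the filter, with a filter at 5 FPKM, with equal medians and with quantile normalization, where limma adjusted p lay between 0.0509 and 0.0960. It was also lost without either Phf7 bam library (limma adjusted p = 0.303 and 0.260). Kmn1 lost its call when any 1 of the 4 libraries was left out, with no filter and with the replicate block (limma adjusted p between 0.0616 and 0.182).

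**Figure D1:**
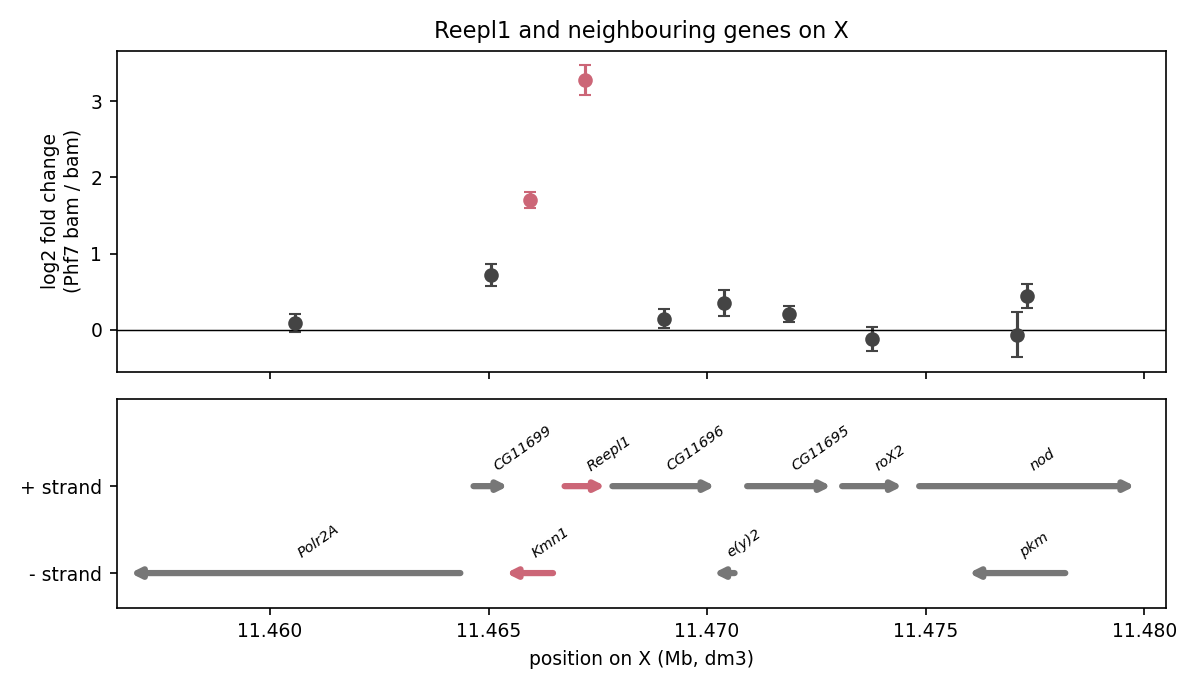
Genes around Reepl1 on X in dm3. The upper panel gives the log2 fold change of Phf7 bam over bam on the log2(FPKM + 1) scale with its SE for each tested gene, against the middle of its locus in Mb; the lower panel gives each locus as an arrow on its strand. Kmn1 at 1.71 and Reepl1 at 3.27, in red, stand above their neighbours.

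CG2233 (X, 7929765 to 7931533) fell from 277 ± 29.0 to 30.6 ± 4.34 FPKM (SD, n = 2 each), a change of -3.14 (SE 0.153, limma adjusted p = 0.00640). CG3526 (X, 2784801 to 2788265) was at 14.7 and 14.6 FPKM in the bam libraries, at 0.06 FPKM in Phf7 bam replicate 1 and listed at 0 in replicate 2 (limma adjusted p = 0.00347). The calls of CG2233 and CG3526 were lost without either Phf7 bam library, with limma adjusted p between 0.0720 and 0.142, and that of CG3526 also with a filter at 5 FPKM (limma adjusted p = 0.0519).

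In all, limma called 11 of 8965 genes higher and 10 lower in Phf7 bam testes, and 550 genes had an unadjusted p under 0.05. Of the 21 called genes 10 had loci under 200 bp, which hold small nucleolar, transfer and spliceosomal RNAs, and 7 longer genes were listed at 0 in at least 1 library. Only Kmn1, Reepl1, CG2233 and Phf7 were longer and above 0 in all 4 libraries. All 21 had the same sign between Phf7 bam replicate 2 and bam replicate 1 alone. These libraries are part of the fit that gave the calls, so this is no separate check. Without Phf7 bam replicate 1 no gene was called by limma, with 1432 at an unadjusted p under 0.05, and without replicate 2 none was called, with 979. Leaving out bam replicate 1 gave 38 higher and 38 lower, and leaving out bam replicate 2 gave 45 and 56. Equal medians and quantile normalization each gave 7 higher and 11 lower.

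The small RNAs that were higher in Phf7 bam testes were listed at 0 in both bam libraries. They were snoRNA:Me28S-G2703b (2R, 10511269 to 10511355) at 512 and 1056 FPKM, snoRNA:Me28S-C788a (3L, 827312 to 827383) at 377 and 103 FPKM, and the U5 gene snRNA:U5:23D (2L, 3048701 to 3048831) at 6.95 and 5.68 FPKM. The glutamine tRNA genes, on 3L, 3R and X, tRNA:Gln-TTG-1-1, tRNA:Gln-TTG-1-2, tRNA:Gln-TTG-1-3 and tRNA:Gln-TTG-2-1 carried identical values of 31.4 and 25.7 FPKM, so their reads cannot be assigned to a copy. Those that were lower were listed at 0 in both Phf7 bam libraries: snoRNA:Me18S-A28a (2R, 13590607 to 13590673) at 956 and 390 FPKM in bam, snoRNA:Me28S-G764 (3L, 22862645 to 22862722) at 89.5 and 73.0 FPKM, and snoRNA:Psi18S-640f (2L, 20421475 to 20421600) at 28.3 and 15.4 FPKM. The limma adjusted p of these 10 genes lay between 0.00156 and 0.0462. The genotype listed at 0 adds no spread, so these p-values rest on the spread of the other genotype and the prior. RNA was selected with oligo-dT beads, which bind poly(A) tails, and most small RNAs of this kind carry none. All 10 lost their calls without either Phf7 bam library. Robust moderation did not call snoRNA:Me28S-C788a (limma adjusted p = 0.255) or snoRNA:Me18S-A28a (limma adjusted p = 0.112). The call of snoRNA:Me28S-C788a was also lost with no filter, equal medians, quantile normalization and moderation without trend (limma adjusted p between 0.0752 and 0.133). That of snRNA:U5:23D was lost with both other pseudocounts, equal medians, quantile normalization and the replicate block (between 0.0519 and 0.132), and that of snoRNA:Psi18S-640f with no filter, equal medians and quantile normalization (between 0.0799 and 0.0955).

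Among longer genes listed at 0 in both libraries of a genotype, the pseudogene CR6900 (CG6900 in the tables; X, 18679838 to 18680243) was at 34.2 and 43.4 FPKM in Phf7 bam testes, and SCOT (CG1140 in the tables; 3L, 1963143 to 1966808), a ketone body enzyme, was at 5.57 and 5.17 FPKM. In the opposite direction, CG5835 (3R, 14974351 to 14985600) was at 39.3 and 37.8 FPKM in bam testes, the exosome subunit Csl4 (2L, 11122564 to 11123792) at 21.0 and 20.6 FPKM, and CG3862 (2L, 824329 to 825861) at 15.7 and 15.5 FPKM. limma called each of these 5 genes (adjusted p between 0.00156 and 0.0492), and none without either Phf7 bam library. SCOT lost its call in 8 settings, with limma adjusted p between 0.0523 and 0.169. As for the small RNAs, the genotype listed at 0 adds no spread, and the p-values rest on the other genotype and the prior. Each of the 5 loci overlaps another gene, CG5835 with nanos by 2639 bp and the others by 9 to 86 bp. Reads of the shared stretches cannot be told apart without strand. Single libraries also list genes used by every cell at 0, with ThrRS at 0 in bam replicate 2 and at 114 to 129 FPKM in the other 3 libraries.

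With robust moderation, limma called 217 genes higher and 90 lower. The prior degrees of freedom were then infinite. Except for the most variable genes, the spread of a gene is then set by its expression level and not by its own replicates. The genes below were called there and in the screened set with robust moderation (210 higher and 95 lower), but not with the standard moderation of the 8965 genes. With the crossed pairing of libraries all of them but Lcp9 and Tbh were called (limma adjusted p between 0.000147 and 0.04998). That pairing was picked from the same values, which lowers the residual spread, so it is no separate support. The genes below were chosen after their values were seen, from the 15 largest increases and 15 largest decreases of the screened robust set. Only genes with both Phf7 bam libraries beyond both bam libraries could enter, so that separation is no result. Not all of these genes are named, and some left out changed more than some that are named. Among them, Cpr92F (0.44 ± 0.0061 and 5.58 ± 1.40 FPKM in bam and Phf7 bam, SD, n = 2 each), Cpr49Ae (0.87 ± 0.590 and 6.64 ± 0.0178 FPKM) and Acp65Aa (0.47 ± 0.277 and 3.09 ± 0.0443 FPKM), which encode cuticle proteins, were higher in Phf7 bam testes with robust moderation (limma adjusted p between 2.00e-19 and 9.39e-08), and had limma adjusted p between 0.116 and 0.270 with the standard moderation. Another cuticle gene, Lcp9, was lower, at 2.63 ± 1.79 and 0.63 ± 0.215 FPKM (SD, n = 2 each; limma adjusted p = 0.836, and 0.000775 with robust moderation), and cuticle genes were not tested as a list. The peptide hormone gene CCHa2 was at 5.98 ± 1.70 and 19.4 ± 2.65 FPKM (SD, n = 2 each), and Pepck1, an enzyme of gluconeogenesis, at 10.6 ± 1.71 and 26.7 ± 1.25 FPKM. Their changes were 1.56 and 1.26, with limma adjusted p = 0.175 and 0.121 (2.14e-19 and 1.42e-13 with robust moderation). Lower values in Phf7 bam testes were found for Hasp (CG10186 in the tables), at 18.5 ± 2.08 and 2.42 ± 1.01 FPKM, for the amyloid precursor homologue Appl, at 6.92 ± 0.0056 and 1.63 ± 0.0843 FPKM, and for Tbh, an enzyme of octopamine synthesis, at 2.85 ± 0.166 and 0.63 ± 0.168 FPKM (SD, n = 2 each). These had limma adjusted p = 0.0715, 0.0715 and 0.310 (1.19e-44, 1.03e-12 and 1.78e-05 with robust moderation).

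**Figure D2:**
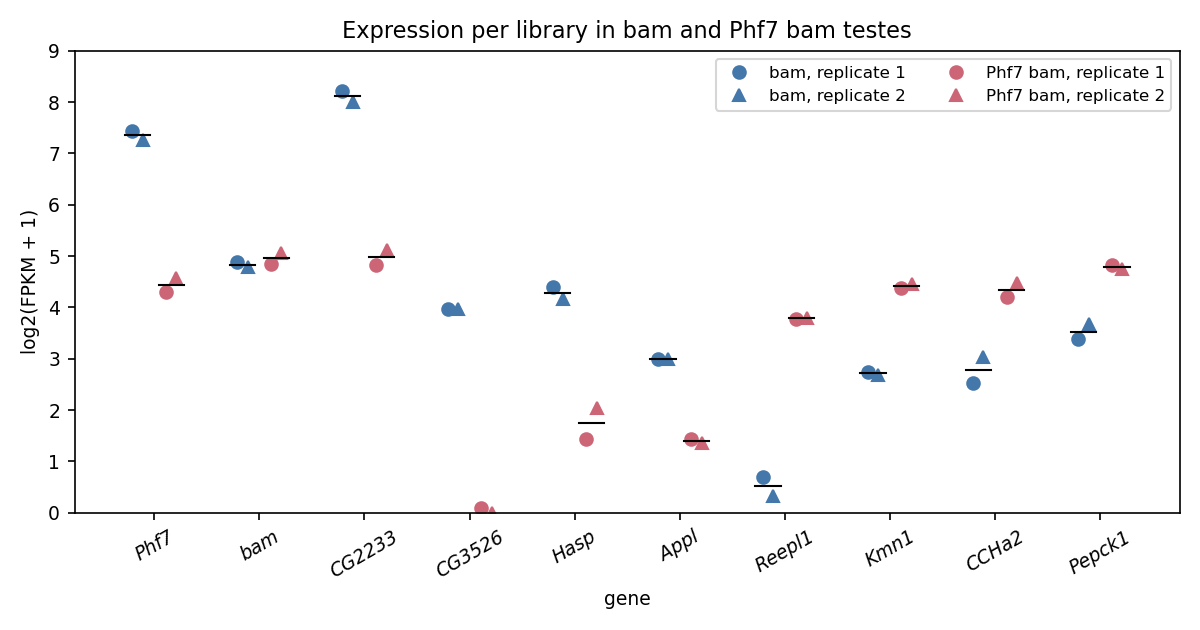
Expression of 10 genes per library as log2(FPKM + 1), with bam in blue and Phf7 bam in red, replicate 1 as a circle and replicate 2 as a triangle; the line is the mean of the 2 libraries and is left out for CG3526, which is listed at 0 in a library. Phf7, CG2233, Hasp and Appl lie lower, and Reepl1, Kmn1, CCHa2 and Pepck1 higher, in both Phf7 bam libraries, and bam overlaps between genotypes.

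No member of the 22 tested lists was called by limma; of 340 such genes 31 had an unadjusted p under 0.05 and 21 were called with robust moderation. Of the early germline list, 0 of 15 measured members were called, with vas, an RNA helicase of germ cells, at 180.3 ± 10.9 and 179.8 ± 9.06 FPKM (SD, n = 2 each), and the list's camera adjusted p was 0.562. esg, a stem cell regulator named after its values were seen, was at 2.80 ± 0.138 and 1.24 ± 0.0333 FPKM (SD, n = 2 each; limma adjusted p = 0.578, and 0.0294 with robust moderation). In the screened robust set nanos of the same list, which overlaps CG5835, was called higher, at 132.6 ± 4.86 and 187.9 ± 23.7 FPKM (limma adjusted p = 0.610, and 0.0317 in that set). None of 11 spermatocyte regulators was called (mip40 at 46.3 ± 3.97 and 49.9 ± 1.66 FPKM; camera adjusted p = 0.562). Of these 11, 4 had an unadjusted p under 0.05, and the screened robust set called topi higher (2.84 ± 0.279 and 4.91 ± 1.17 FPKM) and Rbp4 lower (2.74 ± 0.327 and 1.29 ± 0.347 FPKM; limma adjusted p = 0.0267 and 0.0171 there, and 0.731 and 0.705 over the 8965 genes). Also uncalled were 7 spermiogenesis genes (gdl at 7.52 ± 0.0177 and 7.01 ± 1.16 FPKM; 0.562), 4 testis-specific proteasome genes (Rpt4R at 56.7 ± 6.04 and 62.6 ± 9.05 FPKM; 0.736) and 19 genes of the piRNA pathway (0.816). In the cup and comet group of late spermatid transcripts only 2 genes were measured, with m-cup at 14.3 and 13.2 FPKM in bam and at 12.3 and 13.7 FPKM in Phf7 bam testes, and of the Y-linked list 0 were, so neither was tested. For oogenesis, 0 of 18 measured members were called (me31B at 107.5 and 106.3 FPKM in bam and at 107.6 and 122.3 FPKM in Phf7 bam testes; camera adjusted p = 0.202), though png, a kinase of the egg-to-embryo transition, passed when adjusted over the list alone, at 5.57 ± 0.0503 and 2.37 ± 0.338 FPKM. No axoneme gene of 5 was called (Oseg1 at 7.15 ± 0.555 and 6.95 ± 0.805 FPKM; camera adjusted p = 0.960), and Oseg2 passed when adjusted over the list alone. png and Oseg2 had limma adjusted p = 0.248 and 0.223 over all genes.

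In regulator and housekeeping lists 0 members passed when adjusted over the list alone. These were sex determination (12 measured; snf at 118.9 ± 4.09 and 120.6 ± 10.1 FPKM; camera adjusted p = 0.417), the somatic gonad (16; chinmo at 41.2 ± 2.74 and 35.3 ± 4.65 FPKM; 0.562), JAK-STAT signalling (11; Stat92E at 76.7 ± 1.48 and 83.0 ± 9.09 FPKM; 0.598), H3K4 methylation (13; Dpy-30L1 at 119.8 ± 4.63 and 137.8 ± 26.2 FPKM; 0.562), the cell cycle and replication (21; PCNA at 299.6 ± 18.5 and 300.8 ± 39.8 FPKM; 0.417) and ribosomal proteins (83; RpL41 at 6979 ± 259 and 8169 ± 739 FPKM; 0.230). Robust moderation called the yolk protein gene Yp3 of the sex determination and fat body lists higher, at 8.77 ± 1.16 and 12.9 ± 1.07 FPKM (SD, n = 2 each; limma adjusted p = 0.595, and 0.0457 with robust moderation). nanos, topi, Rbp4 and Yp3 were named after their values were seen. A p that misses the threshold at n = 2 does not show that values are equal.

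The camera test called 4 lists higher in Phf7 bam testes: heat shock (adjusted p = 0.00205), fat body (0.00205), haemocytes (0.0330) and gut (0.0330). With an estimated correlation each had camera adjusted p = 0.971, and fry gave adjusted p = 0.912 for the first 3 and 0.955 for gut. No list was called by either, and the lowest unadjusted fry p was 0.0780. The correlation was estimated from 2 residual degrees of freedom. All 22 lists then had camera adjusted p of at least 0.971, haemocytes at a correlation of only 0.07 included. The estimates were 0.87 for fat body, 0.41 for heat shock and 0.13 for gut. The 4 calls thus rest on a preset of 0.01 that lies below the estimate of each list. Camera with an estimated correlation could hardly call any list, so its misses do not decide about these 4. With equal medians only the fat body list was called. Of the libraries left out in turn, heat shock kept its call without bam replicate 2 or Phf7 bam replicate 2, fat body without bam replicate 2, haemocytes without bam replicate 1, and gut without bam replicate 1 or Phf7 bam replicate 2. Mean log2 values of the heat shock list were 5.53 and 5.95 in bam replicates 1 and 2, and 6.22 and 5.93 in Phf7 bam. Those of the gut list were 2.30 and 2.51 in bam, and 3.66 and 2.32 in Phf7 bam. In both lists Phf7 bam replicate 2 thus did not lie above bam replicate 2. For fat body and haemocytes the means of both Phf7 bam libraries lay above those of both bam libraries. No member passed the gene-level test. In the heat shock list 14 of 16 members had a positive change, with Hsp83 at 1090 ± 55.1 and 1145 ± 81.7 FPKM, and Hsp70Aa (33.2 ± 4.74 and 58.0 ± 5.93 FPKM, SD, n = 2 each) and Hsp70Ab passed when adjusted over the list alone; these copies are near-identical, and their values are uncertain. All 10 fat body members had a positive change, and Lsp2, a storage protein, and Tsf1, a transferrin, passed when adjusted over the list alone. Lsp2 was at 4.75 ± 3.35 and 18.9 ± 1.21 FPKM, Tsf1 at 8.32 ± 0.516 and 18.5 ± 0.767 FPKM, and Ilp6, the highest member, at 18.6 ± 0.492 and 20.3 ± 2.28 FPKM. Col4a1 stood for haemocytes at 69.5 ± 10.6 and 85.5 ± 10.7 FPKM and Amy-p, an amylase, for gut at 75.8 ± 14.9 and 119.4 ± 22.4 FPKM (SD, n = 2 each). Of 18 immune genes, TotC and Tsf1 were higher and AttC lower when adjusted over the list alone (camera adjusted p = 0.202), and Dso1 was at 1112 ± 46.7 and 1415 ± 81.5 FPKM. No member of the muscle list (20; Act57B at 212.9 ± 44.5 and 226.9 ± 3.29 FPKM; camera adjusted p = 0.562), the neuron list (5; Syx1A at 48.4 ± 2.46 and 51.1 ± 4.01 FPKM; 0.949) or the pigment cell list (5; pr at 58.1 ± 2.40 and 49.6 ± 6.97 FPKM; 0.816) was called.

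The markers of other tissues did not move alike in the libraries. Summed FPKM of the 25 measured accessory gland and ejaculatory duct genes was 273 and 3526 in bam replicates 1 and 2, and 8054 and 509 in Phf7 bam replicates 1 and 2, so that they were high in 1 library of each genotype. Acp95EF, a seminal fluid gene, stood at 18.6, 1095, 2209 and 28.6 FPKM in that order (limma adjusted p = 0.988), and the list had camera adjusted p = 0.562. With the crossed pairing, chosen after seeing the data, which sets bam replicate 1 beside Phf7 bam replicate 2, the list was called higher at the preset correlation (camera adjusted p = 1.10e-15), as it was in the screened set (4.40e-05). The estimated correlation of the list was 0.69, at which it had camera adjusted p = 0.971 without pairing. The test with an estimated correlation could hardly call any list, and it was not run in the crossed or screened settings. Without 1 library the list was called in each case, lower without either replicate 1 and higher without either replicate 2. Between the libraries low in accessory gland RNA, Phf7 bam replicate 2 over bam replicate 1, the median log2 ratio was 0.95 for fat body, 0.44 for haemocytes, 0.40 for heat shock and 0.32 for gut. Between those high in it, Phf7 bam replicate 1 over bam replicate 2, the medians were -0.04, 0.10, 0.18 and 0.99.

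**Figure D3:**
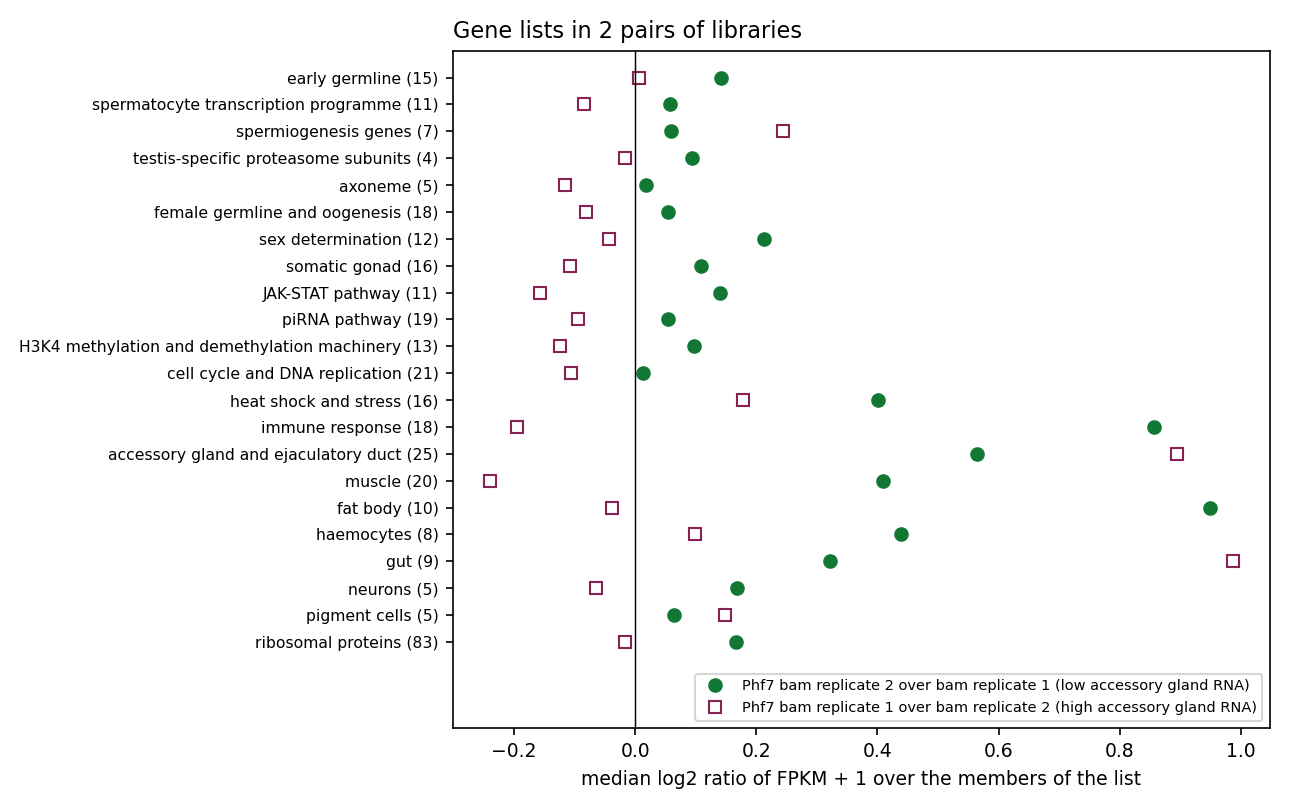
Median log2 ratio of FPKM + 1 over the members of each list, with the number of measured members in parentheses, in Phf7 bam replicate 2 over bam replicate 1 (filled circles) and Phf7 bam replicate 1 over bam replicate 2 (open squares). The fat body list stands at 0.95 in the first pair and at -0.04 in the second.

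Phf7 lies on X, as do Reepl1, Kmn1, CG2233 and CG3526. In the tests of X against the autosomes, Phf7 itself is counted among the lower calls. The glutamine tRNA genes with identical values are counted there as separate genes among the higher calls. Among tested genes on X, 4 of 1512 were called higher, against 7 of 7234 on the autosomes 2L to 3R (Fisher's exact p = 0.106), and 3 were called lower, against 7 (Fisher's exact p = 0.392). With robust moderation, lower calls were more frequent on X, at 32 genes against 56 on the autosomes (odds ratio 2.79, Fisher's exact p = 2.3e-05), and higher calls were at 48 against 164 (odds ratio 1.42, Fisher's exact p = 0.0427). Within 1 Mb of Phf7, Phf7 itself left aside, 0 of 137 genes were called, against 6 called and 1368 uncalled on the rest of X (Fisher's exact p = 1). The median log2 change of all tested genes was 0.03 on X and on the autosomes.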

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

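Settings named as screened or crossed were chosen after seeing the data. Genes called higher numbered 11 and lower 10. They numbered 20 and 17 with a mean FPKM of at least 5, 7 higher with equal medians or quantile normalization, 217 and 90 with robust moderation, 230 and 83 in the screened set, and 210 and 95 in the screened set with robust moderation. Leaving out a library gave 0 to 45 higher and 0 to 56 lower, and the 0s came without either Phf7 bam library. With no calls, these 2 settings gave no odds ratio. The prior degrees of freedom were 2.64, and 134 in the screened set. That set has the same moderation and differs only by leaving out genes with short loci or a listed 0. Leaving these genes out therefore raised the calls from 11 and 10 to 230 and 83. Which of them did so was not tested, nor was the cause of the other differences.

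The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.37 across genes. With the replicate block, 8 genes were called higher and 10 lower, 18 of them among the 21, Phf7 stayed at -2.91, and 4 lists were called. Kmn1 (adjusted p = 0.0616) and SCOT (0.169) lost their calls there. With a crossed pairing, bam replicate 1 with Phf7 bam replicate 2, 98 were called higher and 35 lower, and in the screened set 298 and 112.

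Phf7 kept its direction in 18 of 18 alternatives and missed the threshold in 2, without a Phf7 bam library (-3.05 to -2.77 over the libraries left out; adjusted p over all alternatives from 1.71e-82 to 0.141). Called lists were 4, and 2 with no filter, 3 with a mean FPKM of at least 5, 1 with equal medians, 0 with an estimated correlation, 0 with fry, and 2 to 5 without a library. They were 5 with the crossed pairing, which added the accessory gland list, and 6 in the screened, screened robust and crossed screened settings, which added that list and the immune list, both higher. The odds ratio of higher calls on X, 2.88, passed at 3.52 and 4.06 with pseudocounts of 0.1 and 0.5, at 1.42 with robust moderation and at 1.502 in the screened robust set, and ranged from 0.807 to 1.38 without a library. For lower calls it was 2.23, and passed at 4.16 (pseudocount 0.1), 4.06 (equal medians and quantile normalization), 2.79 (robust), 3.09 (screened), 2.90 (screened robust), 2.35 (crossed), 2.40 (crossed, screened) and 2.27 (without bam replicate 1), and was 0.956 without bam replicate 2. The odds ratio near Phf7, 0.766 from 0 calls, passed in no setting. It stayed under 1 at 0.663 (pseudocount 0.5, no trend), 0.765 (status OK), 0.906 (replicate block) and 0.806 (without bam replicate 1), and turned above 1 at 1.67 and 1.51 with windows of 0.5 and 2 Mb, 1.58 (pseudocount 0.1), 1.13 (no filter), 3.01 (mean FPKM at least 5), 2.31 (equal medians, quantile), 1.37 (robust), 1.60 (screened), 1.39 (screened robust), 1.54 (crossed), 1.28 (crossed, screened) and 1.11 (without bam replicate 2).

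Among named genes only uncalled ones turned sign. With equal medians and quantile normalization the gene snf went to -0.0082 and -0.05 and the gene PCNA to -0.0253 and -0.146. Without a library, changes ranged for vas from -0.0648 to 0.0580, gdl -0.25 to 0.0503, Rpt4R -0.0077 to 0.28, Oseg1 -0.14 to 0.0646, snf -0.0672 to 0.10, Stat92E -0.0022 to 0.22, Dpy-30L1 -0.0068 to 0.38, PCNA -0.13 to 0.14, Hsp83 -0.0021 to 0.14, Acp95EF -2.31 to 3.91, Act57B -0.11 to 0.32 and Syx1A -0.0005 to 0.16. Relative depth differed by up to 1.42 between libraries and the absolute depth is unknown, so no detection limit was set.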

Other observations

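The tests of explanations below, the splits and the genes named here were chosen after the patterns were seen. Beyond the lists, 3 neighbouring genes on X were low together: CG14418, CG14419 and CG3526, within 11667 bp, were at 0.64 and 0.90, 1.38 and 1.26, and 14.7 and 14.6 FPKM in the bam libraries, and were listed at 0 in both Phf7 bam libraries, except CG3526 at 0.06 in replicate 1. CG14418 and CG14419 were under a mean of 1 FPKM and not tested, and a difference of genetic background at this locus was not tested and stays open. EbpIII, an ejaculatory bulb protein, was at 192 ± 17.5 and 370 ± 49.4 FPKM (SD, n = 2 each; limma adjusted p = 0.237, and 1.20e-06 with robust moderation), higher in both Phf7 bam libraries.

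Of the 3 ways to part the 4 libraries into 2 and 2, the genotypes gave 21 calls with limma. Setting bam replicate 2 and Phf7 bam replicate 1 against the other libraries gave 118 calls, and the remaining split gave 1. With robust moderation the counts in that order were 307, 132 and 6. Across genes, which are not independent, log2 values of bam replicate 1 correlated at 0.933 with Phf7 bam replicate 2 and at 0.918 with bam replicate 2. The 118 calls point to a structure of the samples apart from genotype, and 3 splits are too few for a share under 0.05.

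Accessory gland genes were high in bam replicate 2 and Phf7 bam replicate 1, at 0.538% and 1.23% of summed FPKM against 0.042% and 0.077% in the others. None of the 25 measured members is in another list, and 10 were at 1 FPKM or more in both libraries with the lower sums. Against the Phf7 genotype as the whole source, libraries of the same genotype differed by medians of 4.90 and 5.20 on the log2 scale. A smaller effect of genotype stays open: Phf7 bam replicate 2 over bam replicate 1 had a median of 0.56, and Phf7 bam replicate 1 over bam replicate 2 of 0.90. Against library-wide scaling, early germline genes had median log2 ratios of -0.03 and -0.18 between the same libraries. Carry-over of accessory gland in dissection is a candidate explanation. It was looked at in 23 tested Sfp genes, seminal fluid genes outside the list by which the libraries were told apart. The high over the low library had medians of 2.92 in bam and 3.58 in Phf7 bam, and 20 were above both other libraries in both. Most of these genes were under 1 FPKM in both low libraries. They passed the filter on mean FPKM only through the high libraries, so these values are partly set by that filter.

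Several genes were listed at 0 in both libraries of a genotype and at 5 FPKM or more in the other. A failed estimate in quantification is a candidate explanation: 26 protein-coding genes were at 0 in 1 library alone with 5 FPKM or more in the other 3, such as lig at 0 against 280 to 318 FPKM, and 23 of these 26 loci overlapped another gene. All 6 genes at 0 in a same-genotype pair did so too, against 35.4% of the other 7677 tested protein-coding genes (Fisher's exact p = 0.00199). Reads given to the overlapping gene instead stay open for the loci given here, which are not all of them. nanos was at 136 and 129 FPKM in bam and at 171 and 205 FPKM in Phf7 bam testes, where CG5835 was at 0. CG3662 was at 108 and 104 against 142 and 161 FPKM, where CG3862 was at 0. CG1927 was at 67.6 and 72.2 against 52.1 and 59.3 FPKM, where SCOT appeared. The genes overlapping Csl4 and CR6900 differed by -0.07 and -0.13. An effect of the Phf7 genotype cannot be told apart from this: 4 genes were at 0 in the Phf7 bam pair and 2 in the bam pair, while mixed pairs had 0, 7, 1 and 2, and 4 of the 7 were the seminal fluid genes Sfp26Ac, Sfp53D, Sfp70A4 and Sfp77F.

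Reepl1 and Kmn1 were higher in both Phf7 bam libraries. A fixed share of Kmn1 reads counted in Reepl1 is argued against as the whole cause by a change of Reepl1 that was larger by 1.57 (SE 0.22). A fixed share of CG11699 reads counted in Kmn1, which it overlaps by 46 bp, is argued against by a change of Kmn1 that was larger by 0.99 (SE 0.18). Another way of dividing reads, Reepl1 reads counted in Kmn1 among them, stays open. Also argued against are a change of the whole region by a median change of 0.15 in 10 other tested genes within 20 kb, though CG11699 rose by 0.72, and carry-over of accessory gland by differences of at most 0.37 within a genotype. Other tissue present alike in both Phf7 bam libraries stays open, as do an effect of losing Phf7 and a difference of genetic background at this locus, all untested.

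A related hypothesis is that neighbouring genes change together across the genome, and the test does not decide it. Set aside were adjacent pairs with a shared symbol stem or the same first 3 letters, pairs with both loci under 200 bp, and pairs with the same values in every library, such as copies of a tRNA gene. The remaining pairs were non-overlapping and adjacent among tested genes, with no limit on distance. In the screened robust set tsh and CG31601, 203776 bp apart, formed such a pair. Of 6 settings with at least 100 calls, 5 had more remaining pairs called in the same direction than the mean of 10000 permutations along each arm. The one-sided permutation p was at most 0.0006 there, as with 20 pairs against a mean of 5.65 in the screened robust set. These 5 settings are robust, screened or crossed. In the other, without bam replicate 2, 17 of 17 pairs were set aside, and 0 remained against a mean of 0.48 (permutation p = 1). Families with unlike names and clusters of genes of another tissue, such as Sfp60F and EbpII, were not set aside and may account for part of the excess. Among the 21 calls 1 such pair remained, Kmn1 and Reepl1 (permutation p = 0.0197). This pair was seen before the hypothesis was written, so its p is no separate test of it. That pair was also the only one with pseudocounts of 0.1 and 0.5, without trend, at 2-fold and with status OK (permutation p between 0.0137 and 0.0370), so these settings add no other genes. The permutation p was 0.235 without bam replicate 1, and no such pair was called with no filter, a mean FPKM of at least 5, equal medians, quantile normalization or the replicate block.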
